A study of Mus musculus with 6 samples.

How the data were processed

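Dendritic cells isolated from MC38 tumours on day 10 were profiled by RNA sequencing in 6 samples, 3 from wild-type and 3 from MAVS knockout hosts, per the labels. RNA was extracted with Trizol, per the labels' protocols. The deposited values are raw read counts per Ensembl mouse gene, which the authors made before deposit: whole numbers from 0 with a different total in each library. The submitters' processing notes name the mm10 build and the tools HISAT2 (also listed as HISAT), HTSeq and DESeq2, without role, version or settings. The annotation release and the strand setting are not given in the sources used here. Reads from antisense or overlapping partners and from near-identical gene copies could therefore be assigned to either gene. How the cells were sorted or gated is not given in the sources used here.

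The table held 26519 genes, each with at least 1 count in total. Symbols, positions and gene types came from GENCODE M21 on GRCm38 (the mm10 build), which matched 26356 identifiers; 163 did not match. Library totals were 14466640 to 20851733 counts and 15635 to 21432 genes had a count. The 10 most abundant genes took 11.65% to 12.0% of counts in wild-type and 13.63% to 14.54% in knockout libraries. Mitochondrial transcripts took 0.357% to 0.499%. In a principal component analysis of the 500 most variable tested genes, the first component held 38.4% of the variance, with wild-type libraries from -23.8 to -11.9 and knockout libraries from 4.06 to 32.6. Pearson correlations across genes were 0.959 to 0.974 within wild-type, 0.962 to 0.973 within knockout and 0.947 to 0.979 between groups. No libraries were duplicates: chi-square per degree of freedom was 15.9 to 38.8 for pairs within a group.

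Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr (minimum count 10, minimum total 15), TMM scaling, and the quasi-likelihood F test without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. This left 12580 genes. CPM values are TMM-scaled, and SE and 95% intervals are those of the fit. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 33 lists with at least 3 tested members. That minimum was set after the data were seen and leaves out the mast cell list (1 gene) and the erythroid and platelet list (2 genes). The 35 lists, the test, the alternatives other than those named as added, and the rule for named genes were fixed before the data were examined. Some lists share genes, such as Gbp2, Cd274, Cxcl9 and Arg1, so their results are not independent. With the correlation estimated from the data no list was called (0 of 33, smallest adjusted p 0.133), 8 had an unadjusted p below 0.05, and fry called 7. Those 7 were the costimulation, chemokine, glycolysis and hypoxia, cholesterol and lipid, mature migratory, neutrophil and B cell lists.

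Genes are named by a fixed rule: Mavs, Il12a and Il12b always; the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 5 CPM and no overlap between groups, leaving out unnamed gene models, pseudogenes and antigen-receptor segments; and up to 4 members of each list with the smallest p. Lyz2, C1qb, Csf1r, Adgre1, Cd3e, Clec9a, Itgae, Zbtb46, Cx3cr1, Gatm, Eif3j1, Mmp12, Arg2, Slc2a1, Hk2, Egln3, Serpinb2, Ch25h, Inhba and Edn1 fall outside that rule and were chosen after their values were seen. Pcna, Nusap1 and Bub1 also fall outside it and are named for their position near Mavs. Pseudogenes and unnamed models were counted but not named, except as copies of named genes. Of the genes the rule names, 1 is not reported here.

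Alternatives were DESeq2 size factors, library size alone, no filter on low counts, a mean of at least 5 CPM, the DESeq2 1.42.0 Wald test, limma-voom, a block on replicate number, robust dispersion, a log2 fold change of at least 1, leaving out each library, an estimated correlation, and fry. Thinning every library to the smallest total, and leaving out the genes within 15 Mb of Mavs, were added after seeing the data.

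The procedure was tested on simulated counts for this comparison, with 200 changed genes among 12257 tested in each of 5 runs. It recovered 16.8% of 1.5-fold, 53.2% of 2-fold, 83.6% of 4-fold and 92.4% of 8-fold changes, with 6.2% false calls. A list raised 1.5-fold was called by camera in 2 of 2 runs, and lists left unchanged were called 2 times in the 3 runs without it. Genes were simulated independently, so this does not test lists whose members vary together. At this depth and n = 3 per group, most 1.5-fold changes would not be called.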

Results

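RNA sequencing measured the transcripts of tumour-infiltrating dendritic cells, the antigen-presenting cells that prime T cells, taken from tumours grown in mice, in 6 samples: 3 from wild-type hosts and 3 from hosts lacking MAVS. The tumours came from MC38, a mouse colon carcinoma line, and were collected on day 10 after inoculation. MAVS is the mitochondrial adaptor that carries the signal of the RIG-I-like sensors of cytosolic RNA. The comparison asks how loss of host MAVS alters the dendritic cells within the tumour, and the series names interleukin-12 as the cytokine of interest. Library totals were 19201453, 17357031 and 20851733 counts in the wild-type libraries and 18862534, 15897590 and 14466640 counts in the knockout libraries. The labels do not say whether each replicate came from a separate animal, so the p-values measure only the spread between these samples.

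Mavs (ENSMUSG00000037523, chromosome 2, 131234063 to 131248025 in mm10) was lower in all 3 knockout libraries. It stood at 37.7 ± 3.32 CPM (SD, n = 3) in wild-type and 10.4 ± 2.09 CPM (SD, n = 3) in knockout hosts. Its log2 fold change was -1.86 (SE 0.18, adjusted p = 0.0017, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Transcripts therefore remained in the knockout libraries, and the labels do not say which part of the gene was deleted.

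Of the subunits of the interleukin-12 family, Il12a and Il27 rose in knockout hosts and Il12b showed no detectable change. Il12a, which encodes the p35 subunit of interleukin-12, had 0.388 ± 0.148 CPM (SD, n = 3) in wild-type and 3.80 ± 2.24 CPM (SD, n = 3) in knockout libraries, from 7, 5 and 12 counts against 81, 19 and 76 counts. Its log2 fold change was 3.26 (SE 0.64, adjusted p = 0.0303 by edgeR's quasi-likelihood test). That call rests on few counts: with limma-voom the adjusted p was 0.118, and the call was kept only without knockout replicate 2 among the 6 fits that left out a library, with adjusted p from 0.0327 to 0.136. Il27, the p28 subunit of interleukin-27, went from 3.75 ± 1.17 to 14.7 ± 0.687 CPM (SD, n = 3 each), a log2 fold change of 1.97 (SE 0.27, edgeR adjusted p = 0.0107). Il12b, which encodes the p40 subunit, had a log2 fold change of 0.03 (SE 0.69, edgeR adjusted p = 0.99) with a 95% interval from -1.50 to 1.56. Its libraries spread widely, from 0.887 to 5.94 CPM in wild-type and 1.41 to 4.89 CPM in knockout hosts, and the log2 fold change was 1.26 without wild-type replicate 3 and -0.63 without knockout replicate 1, neither of which passed. Ebi3 (0.05, SE 0.19) and Il23a (0.08, SE 0.99) did not pass. As a list, the 5 subunits were called higher by camera (adjusted p = 0.00414), with adjusted p = 0.141 with an estimated correlation. Its members numbered 2 higher and 3 not passing, also when adjusted over the list alone. With limma-voom the list's adjusted p was 0.0658.

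**Figure D1:**
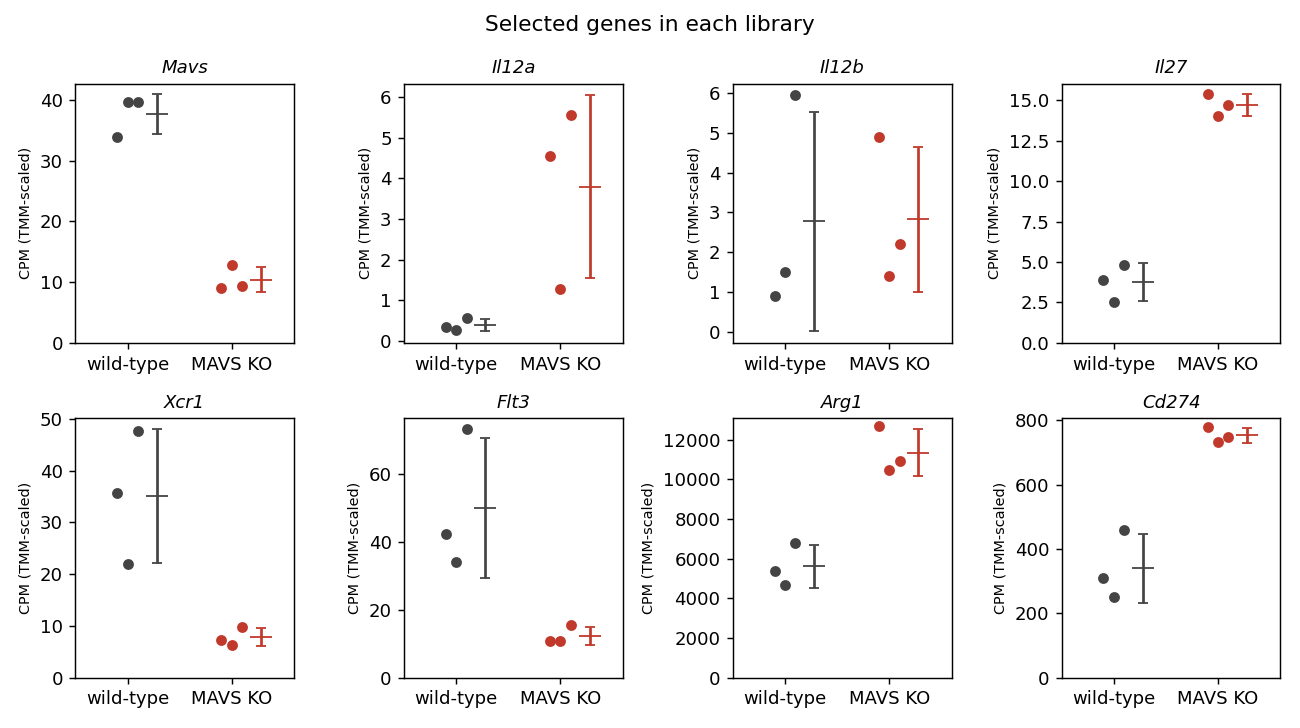
Normalised expression of 8 genes in each library, in TMM-scaled CPM on a linear axis; dots are single libraries, and the bar beside them is the mean with the SD of 3 libraries. Mavs, Xcr1 and Flt3 lie lower and Il27, Arg1 and Cd274 higher in all 3 knockout libraries than in any wild-type library, while the Il12b values of the groups overlap.

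Across the transcriptome, 354 of 12580 tested genes differed between the groups, 222 higher and 132 lower in knockout hosts (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of these, 149 changed by at least 2-fold, 76 higher and 73 lower. Values of the groups did not overlap for any of the 354 genes, a separation that chance gives for 10% of genes and that 21.8% of all tested genes showed. The split depended on scaling: with library size alone it was 102 higher and 341 lower, because the median log2 fold change of all tested genes was then -0.17 against -0.0022 with TMM, and directions here are relative to the TMM median. Without knockout replicate 1, 2 or 3 the count fell to 39, 64 and 36 genes, and without wild-type replicate 1 or 2 to 193 and 151. Of the 354 genes, 23 passed in all 6 such fits.

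The largest rises included an antimicrobial enzyme, a chemokine and a protease. Nos2, the inducible nitric oxide synthase, rose by 2.43 on the log2 scale (SE 0.43), Chil3, a chitinase-like lectin, by 2.46 (SE 0.51), the eosinophil-attracting chemokine Ccl24 by 2.77 (SE 0.63) and the collagenase Mmp13 by 2.40 (SE 0.35). The carbonic anhydrase Car4 rose by 2.31 (SE 0.42), Asb11 by 1.99 (SE 0.33) and Wdfy1 by 1.99 (SE 0.28). Ccl24, Chil3 and Nos2 lost their call with robust dispersion estimation, as did Ccl24 with limma-voom. The other named rises, Tmem87a at 4.13 (SE 0.23) and Eif3j2 at 4.98 (SE 0.32), belong to the region around Mavs or to a near-identical gene copy. Eif3j2 matches Eif3j1 at 99.4% of its 2379 bases, and the summed counts of both changed by -0.14 (95% interval -0.41 to 0.14, edgeR adjusted p = 0.668), so the values of Eif3j1 and Eif3j2 taken singly are uncertain.

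The largest falls included Xcr1, Snx22 and Gcsam, which are in the list of type 1 conventional dendritic cell (cDC1) markers. Xcr1, the chemokine receptor that marks these cells, went from 35.1 ± 12.9 to 7.79 ± 1.75 CPM (SD, n = 3 each), a log2 fold change of -2.18 (SE 0.29, edgeR adjusted p = 0.00994). Flt3, the receptor for the growth factor on which dendritic cells depend, changed by -2.01 (SE 0.28), Btla, an inhibitory receptor, by -2.26 (SE 0.23), Cxcr3 by -2.25 (SE 0.36), Snx22 by -2.44 (SE 0.39) and Gcsam by -2.08 (SE 0.42). Siglecg (-2.01, SE 0.40), Ipcef1 (-2.25, SE 0.43) and Gpr141b (-2.25, SE 0.48) complete the falls apart from Spint1, at -8.12 (SE 0.46), which lies near Mavs. Gpr141b, Ipcef1 and Gcsam lost their call with limma-voom. Of the 20 genes with the largest rises and falls, Eif3j2, Tmem87a, Wdfy1, Il27, Spint1, Btla and Xcr1 passed in each fit that left out a library.

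Markers of 4 dendritic cell subsets were tested as lists, which were not compared with each other. Of 17 cDC1 markers, 6 fell, 1 rose and 10 did not pass (8 lower and 1 higher when adjusted over the list alone). The median log2 fold change was -0.66 (camera adjusted p = 2.73e-07, adjusted p = 0.255 with an estimated correlation). Itgae (-1.85), Zbtb46 (-1.20) and Wdfy4 (-0.96) fell with Xcr1, whereas Id2 rose by 0.51, and Clec9a, a cDC1 receptor for dead cells, had a log2 fold change of -0.07 (SE 0.28). Zbtb46 and Id2, though in the list, are not restricted to cDC1. Among 24 markers of mature migratory dendritic cells, 4 rose and 2 fell, or 8 and 2 when adjusted over the list alone, with a median of 0.44 (camera adjusted p = 0.00112, adjusted p = 0.133 with an estimated correlation). The lymph-node homing receptor Ccr7 rose by 1.12 (SE 0.22), Ccl22 by 0.95 and Cd200 by 1.82, while Tmem176a (-1.74) and Tmem176b (-1.63) fell. For type 2 conventional dendritic cells, Cd209a fell (-1.86) and Sirpa rose (0.56) among 15 markers, 13 not passing, and the list was not called (camera adjusted p = 0.991). Its median was positive and its mean and test negative. Adjusted over the list alone, 2 rose and 1 fell. Sirpa lies within 15 Mb of Mavs. None of 10 plasmacytoid markers passed over all genes, and 1 was lower adjusted over the list alone (camera adjusted p = 0.809).

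The libraries also held abundant macrophage transcripts in both groups. Lyz2 stood at 21636 ± 2363 CPM in wild-type and 22105 ± 4494 CPM in knockout hosts (SD, n = 3 each), and C1qb at 2151 ± 256 and 2695 ± 196 CPM. Neither passed, nor did Csf1r (-0.07, SE 0.11) or Adgre1 (-0.24, SE 0.15). Of 23 macrophage markers 2 rose, Arg1 by 1.01 (SE 0.13), an arginine-degrading enzyme, and the Fc receptor Fcgr4 by 1.27, with 11 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.000256, adjusted p = 0.237 with an estimated correlation). Of 10 neutrophil markers 2 rose, Mmp8 by 1.10 and Acod1 by 1.78, the same number when adjusted over the list alone plus 1 lower (camera adjusted p = 8e-04, adjusted p = 0.133 with an estimated correlation); Acod1 is also made by activated macrophages. In the monocyte list Chil3 rose and Thbs1 fell (-1.84), both calls lost with robust dispersion estimation, with 3 higher and 2 lower adjusted over the list alone and no call (camera adjusted p = 0.852, median and test negative, mean positive). Thbs1 lies within 15 Mb of Mavs.

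Markers of lymphocytes and of non-haematopoietic cells were tested as lists. Of 5 detected B cell markers Ighm fell (-1.93) and 3 fell when adjusted over the list alone (camera adjusted p = 8e-04, adjusted p = 0.133 with an estimated correlation). Of 5 endothelial markers Flt1 rose (1.89), with 3 higher adjusted over the list alone (camera adjusted p = 0.00702, adjusted p = 0.177 with an estimated correlation). Il7r rose by 1.07 among 22 T cell markers, with Cd3e at 0.585 ± 0.413 and 1.05 ± 0.462 CPM (SD, n = 3 each), and that list was not called (camera adjusted p = 0.884). Its median was negative and its mean and test positive, and adjusted over the list alone 1 was higher and 1 lower. Natural killer (16 genes, adjusted p = 0.468), tumour epithelial (9 genes, adjusted p = 0.178) and fibroblast lists (15 genes, adjusted p = 0.988) were not called by camera and had no member passing, also when adjusted over the list alone. For fibroblasts the median and mean were positive and the test negative. Kit, the single detected mast cell marker, fell (-1.27), and neither of the 2 detected erythroid and platelet markers passed.

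Of 33 genes induced by interferon-gamma 11 rose, none fell and 22 did not pass, or 25 rose when adjusted over the list alone, with a median log2 fold change of 0.68 (camera adjusted p = 8.31e-24, adjusted p = 0.177 with an estimated correlation). They included the guanylate-binding protein Gbp2 (1.21, SE 0.21), Serpina3g (1.08, SE 0.16) and Cd274 (1.15, SE 0.18), the ligand of the inhibitory receptor PD-1, which went from 339.5 ± 107 to 753 ± 23.2 CPM (SD, n = 3 each). Of 49 type I interferon-stimulated genes 4 rose, Rsad2 (1.19), Slfn1 (1.13), Ifit2 (0.87) and Gbp2, which is also in the interferon-gamma list, with 9 higher adjusted over the list alone (median 0.18, camera adjusted p = 0.00128, adjusted p = 0.70 with an estimated correlation). Without wild-type replicate 2 that list's median was -0.02 and its camera adjusted p 0.404. Of 22 genes of MHC class I presentation 5 rose, including H2-K1 (0.51), H2-Q6 (0.78) and B2m (0.65), or 12 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.19e-09, adjusted p = 0.234 with an estimated correlation); B2m lies within 15 Mb of Mavs. The MHC class II list was not called (camera adjusted p = 0.35), although Ctss (0.53) and Lgmn (0.50), its lysosomal proteases, rose, the same 2 when adjusted over the list alone.

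Of 21 chemokines 5 rose, 16 did not pass and 10 were higher adjusted over the list alone (median 0.49, camera adjusted p = 9.28e-10, adjusted p = 0.133 with an estimated correlation), with Ccl6 at 0.99, Cxcl9 at 0.99 (call lost with limma-voom) and Cxcl2 at 0.49 beside Ccl22 and Ccl24. Of 19 costimulatory and coinhibitory genes 5 rose (6 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000855, adjusted p = 0.133 with an estimated correlation), including the PD-1 ligands Cd274 and Pdcd1lg2 (1.63) and Cd40 (0.71). Sirpa, also among the 5, lies within 15 Mb of Mavs. Of 14 cytokines Il1a (0.97, within 15 Mb of Mavs) and the interleukin-1 antagonist Il1rn (0.73) rose, with 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000855, adjusted p = 0.212 with an estimated correlation). Of 32 members and targets of NF-kB 4 rose, among them Ptgs2 (0.85) and Sod2 (0.64), or 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000747, adjusted p = 0.177 with an estimated correlation). Chemokine receptors and adhesion molecules went both ways, 3 higher, such as Ccr7, and 4 lower (Cx3cr1, Cxcr3, Itgae and Xcr1) of 22, the same numbers adjusted over the list alone, with no call (camera adjusted p = 0.579) and a median above and a mean and test below 0.

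In the pathway of MAVS itself, Mavs was the sole member of 20 to pass, over all genes and adjusted over the list alone, and the list was not called (camera adjusted p = 0.701; median positive, mean and test negative). Of 24 genes of the cGAS-STING and Toll-like receptor pathways Ifi204 (0.79) and Tlr4 (0.47) rose, with 4 higher adjusted over the list alone and no call (camera adjusted p = 0.0601).

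Part of the cell cycle genes fell and part of the genes of glycolysis and hypoxia rose. All 35 cell cycle genes had negative log2 fold changes, 13 fell over all genes and 28 adjusted over the list alone, with a median of -0.76 (camera adjusted p = 4.46e-28, adjusted p = 0.177 with an estimated correlation). The replication helicase subunits Mcm2 (-1.06), Mcm3 (-0.94) and Mcm5 (-1.11) and the mitotic checkpoint kinase Bub1b (-1.48) were among them. Bub1b, Pcna, Nusap1 and Bub1 lie within 15 Mb of Mavs. Pcna, 1 of the 28, has a pseudogene copy that matches it at 99.2% of the 781 bases of the copy, and the summed counts of both changed by -0.31 (SE 0.13, edgeR adjusted p = 0.262), so its value taken singly is uncertain. Of 34 genes of glycolysis and hypoxia 14 rose and none fell, or 28 rose adjusted over the list alone, with a median of 0.50 (camera adjusted p = 6.07e-24, adjusted p = 0.133 with an estimated correlation). Hilpda (0.81, SE 0.10), Ndrg1 (1.04, SE 0.16) and the glycolytic enzyme Tpi1 (0.57, SE 0.09) passed, and Arg1 went from 5621 ± 1087 to 11346 ± 1160 CPM (SD, n = 3 each). Of 32 genes of cholesterol synthesis and lipid handling 3 rose, Fabp5 (1.16), Scd2 (0.62) and Msr1 (0.55), with 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00414, adjusted p = 0.133 with an estimated correlation). With library size alone the medians of that list and of the interleukin-12 family turned to -0.07 and -0.08, while both stayed called as higher than other genes.

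The lists that track sample quality were not called. The dissociation-induced genes (29 tested, camera adjusted p = 0.893, with a negative median and a positive mean and test), mitochondrially encoded genes (12 tested, adjusted p = 0.35) and ribosomal protein genes (41 tested, adjusted p = 0.287) were not called, although Nr4a2 (-0.89) and Rpsa (-0.68) fell. A pseudogene copy of Rpsa matches it at 99.3% of the 885 bases of the copy, and the summed counts of both changed by -0.35 (SE 0.15, edgeR adjusted p = 0.267), so Rpsa did not pass once reads of the copy were added. With library size alone the ribosomal list was called lower, at a median of -0.22 (camera adjusted p = 0.0161). Oxidative phosphorylation (39 tested, adjusted p = 0.717) and the unfolded protein response (25 tested, adjusted p = 0.706) were not called and had no member passing. Adjusted over the list alone, Nr4a2 and Rpsa remained the sole members of these 5 lists to pass.

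**Figure D2:**
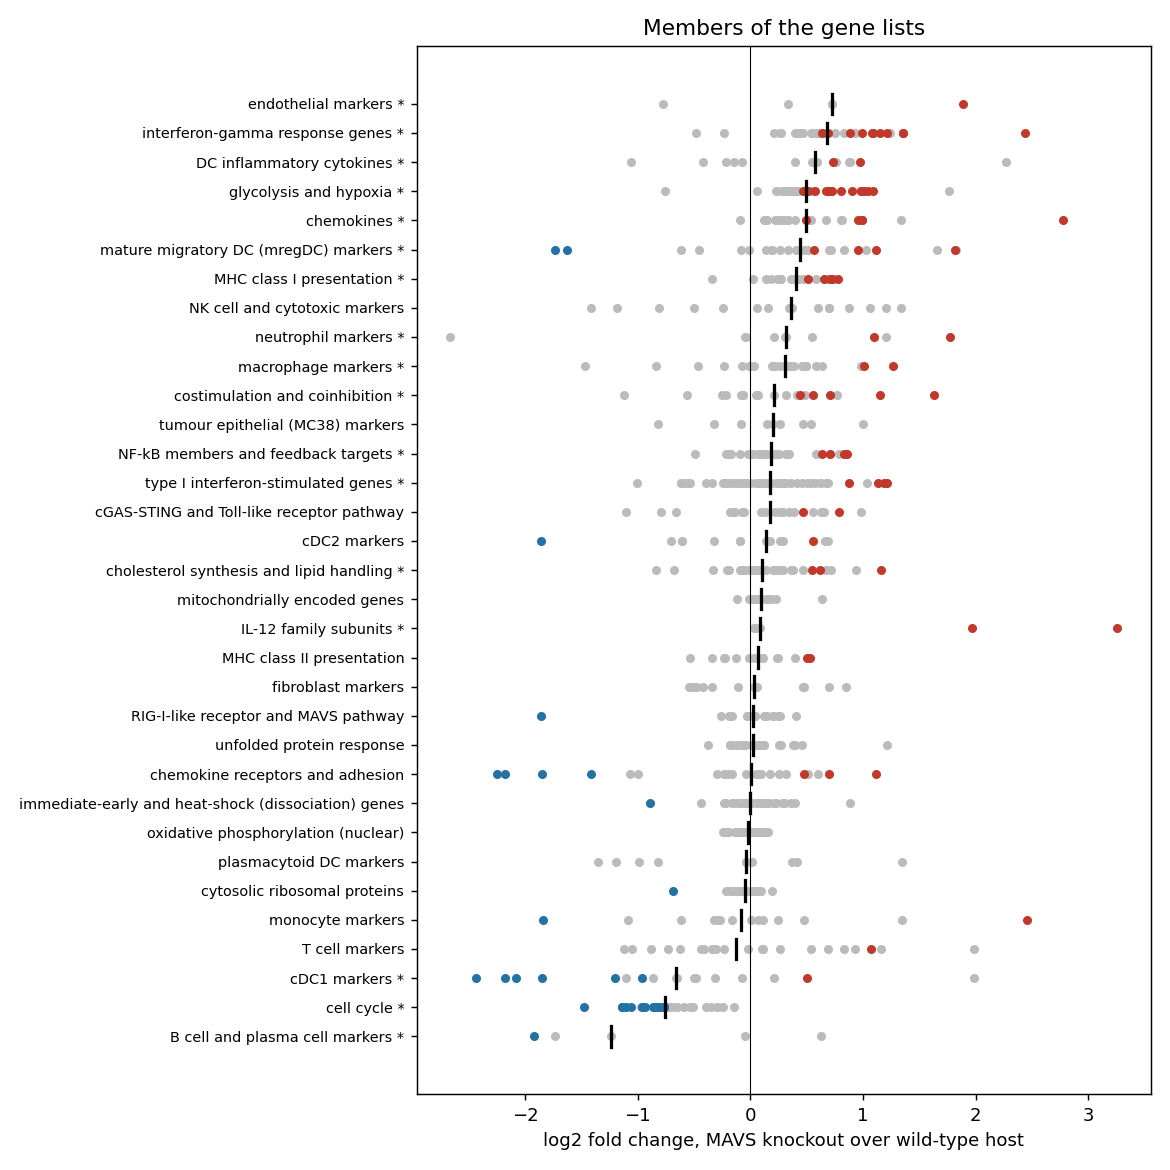
Log2 fold change (knockout over wild-type hosts) of each tested member of 33 gene lists, ordered by list median (black bar); red and blue dots are genes that rose or fell by edgeR's test and grey dots did not pass. An asterisk marks the 17 lists called by camera with its preset correlation; cell cycle genes lie to the left of 0 and most genes of glycolysis and hypoxia to the right.

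Called genes were concentrated near Mavs. Within 15 Mb of it 25 of 206 tested genes passed (12.1%), against 329 of 12352 elsewhere (2.66%). They went both ways, 12 higher and 13 lower. Spint1 (chromosome 2, 119237362 to 119249527), a protease inhibitor, went from 270 ± 42.7 to 0.939 ± 0.830 CPM (SD, n = 3 each), and Tmem87a (chromosome 2, 120355312 to 120404113) from 3.84 ± 1.08 to 66.8 ± 11.5 CPM. Gatm, an enzyme of creatine synthesis in the same region, rose by 1.76 (SE 0.16). The 25 genes include Eif3j1, whose own value is uncertain.

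**Figure D3:**
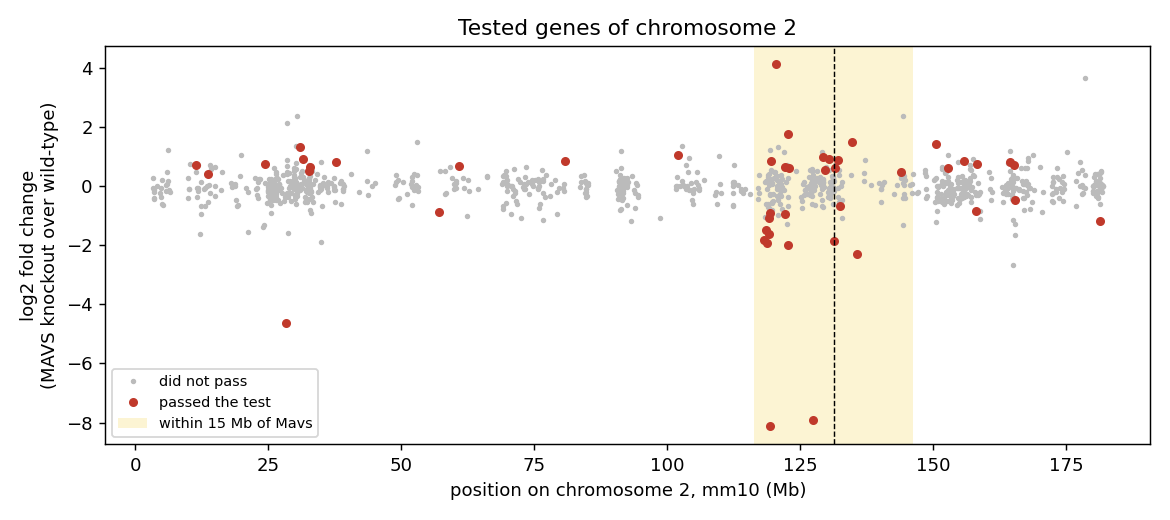
Log2 fold change (knockout over wild-type hosts) of the tested genes of chromosome 2 by position in mm10, in Mb; red dots passed edgeR's test and grey dots did not. The dashed line marks Mavs and the shaded band the 15 Mb on either side, which hold 25 called genes.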

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

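Thinning to equal depth and leaving out genes near Mavs were chosen only after the results were seen; the other alternatives were fixed before the data were examined. Mavs passed in each refit that gave it a value, with log2 fold changes from -2.03 to -1.76, and Il12b in none. No called direction of a named gene reversed under another scaling, filter or test. The 354 changed genes, 222 higher and 132 lower, became 924 (531 higher, 393 lower) without a filter on low counts, 738 (412 and 326) with the DESeq2 Wald test and 149 (76 and 73) with a log2 fold change of at least 1. With library size alone they became 102 higher and 341 lower, and 19 of 78 called named genes lost their call. The DESeq2 test kept 352 of the 354 genes. The cause of the larger counts was not tested. Leaving out 1 library gave 36 to 277 changed genes, 22 to 181 higher and 9 to 96 lower: 39, 64 and 36 without knockout replicates 1, 2 and 3, and 193, 151 and 277 without wild-type replicates 1, 2 and 3. Fewer samples lower the power of each such fit. Il12a had 3.01 with limma-voom, past no threshold, and 2.89 to 3.67 with a library left out, passing only without knockout replicate 2 (adjusted p 0.0327, against 0.0553 to 0.136 in the others). Called lists numbered 11 for pathways and quality and 6 for cell types, 0 and 0 with an estimated correlation, and 4 and 3 with fry. Thinning gave 364 genes and leaving out genes near Mavs 313.

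Replicate numbers showed no clear pairing of the samples. The correlations of same-numbered deviations were 0.04, 0.09 and -0.04, and 3 of 6 libraries correlated best with their own number. With 3 libraries per group, this check cannot exclude a pairing. With the replicate block 414 genes changed (264 higher, 150 lower). These included 311 of the 354 genes of the main fit, and 3 of 78 called named genes lost their call. No set test was run with robust dispersion, and Il12a and Il12b fall below the filter of 5 CPM.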

Other observations

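All tests of explanations in this part were chosen after the results they bear on had been seen. Those for a smaller share of cDC1 and of cycling cells also replaced an earlier test of whether the markers fell equally, after its outcome was seen. That test treats correlated genes as independent, and it had counted against both explanations. The test for a smaller share of every dendritic cell type replaced the change of Ccr7 alone (1.12, 95% interval above 0), which had counted against it, after that value was seen. The test of GC content and length replaced a correction for their trend, which moved almost nothing (SD of the trend 0.022). The real grouping of the 6 libraries called 354 genes and the highest of the other splits called 1; 1 of the 10 splits reached the real count, and 10 splits are too few for a share under 0.05.

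Several abundant or strongly changed genes that were not described above rose in knockout hosts. The macrophage elastase Mmp12 went from 6916 ± 1637 to 15335 ± 2356 CPM (SD, n = 3 each; log2 fold change 1.15), and the mitochondrial arginase Arg2 rose by 0.96 beside Arg1 and Nos2, which compete for arginine. Of the glycolysis and hypoxia list, the prolyl hydroxylase Egln3 rose by 1.09, the glucose transporter Slc2a1 by 0.67 and the hexokinase Hk2 by 0.70. Outside the lists, Serpinb2 rose by 1.84, Ch25h, the enzyme of 25-hydroxycholesterol synthesis, by 1.73, Inhba by 1.65 and Edn1 by 1.09 (each past edgeR's adjusted threshold).

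Called genes crowded around Mavs. The odds ratio of a call within 15 Mb was 5.05 (95% interval 3.14 to 7.82, Fisher's exact test, two-sided p = 7.36e-10). Fisher's test takes genes as independent, and neighbours or co-regulated genes may vary together, so the intervals given here may be too narrow. Of 263 other windows as wide none had as high a share, the highest being 7.53% on chromosome 19. Those windows were moved by 5 Mb and so overlap, and windows with few tested genes were left out. Loss of MAVS signalling acting alike at every position is argued against as the whole cause, since the ratio was 4.85 (2.98 to 7.56) with Mavs itself left out. Effects on near neighbours alone are argued against too: the called share was 11.4% within 5 Mb, 12.7% at 5 to 15 Mb and 3.39% at 15 to 30 Mb, and the ratio at 5 to 15 Mb was 5.32 (2.84 to 9.31). A stretch of another strain's DNA carried with the mutation may account for these genes. It cannot be told apart from effects of the mutation over a longer range, since the strains are not given. Of 253 windows of 10 Mb, 3 held an excess, 1 of them on chromosome 16. That window had the highest share of the 3, 20.7% (6 of 29 genes), against 14.5% and 15.2% for those on chromosome 2.

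Of 17 cDC1 markers 6 fell, and of 23 macrophage markers Arg1 and Fcgr4 rose, in lists whose calls are lost with an estimated correlation (camera adjusted p = 0.255 and 0.237). A larger macrophage share is argued against as the cause of the rise of Arg1, since Arg1 changed by 1.09 more than Csf1r (95% interval 0.70 to 1.47). A smaller share of every dendritic cell type stays open: the median of the mature migratory list was 0.44, but genes induced on maturation can rise per cell, and Tmem176a, Tmem176b, Flt3, Zbtb46 and Cd209a fell. A smaller share of cDC1 could account for the falls of Xcr1, Snx22 and Gcsam, but Clec9a did not follow, its change lying 2.11 above that of Xcr1 (95% interval 1.22 to 2.99). That leaves open both fewer cDC1 and lower expression per cell, which cannot be told apart here, since other cells may also express Clec9a.

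Of 35 cell cycle genes 13 fell, while 14 of 34 genes of glycolysis and hypoxia and 11 of 33 of the interferon-gamma response rose, in lists whose calls are lost with an estimated correlation (camera adjusted p = 0.177, 0.133 and 0.177). The glycolysis and hypoxia list was called by fry (adjusted p = 0.0304), whereas the cell cycle (fry adjusted p = 0.0683) and interferon-gamma lists (fry adjusted p = 0.0697) were not. Thinning does not settle the part of lower depth: at equal depth the cell cycle median was -0.77, with 0.48 and 0.66 for the other lists. The fit already scales for library totals, so thinning could hardly have moved these medians. Totals also overlapped between groups, at 18862534 counts in knockout replicate 1 and 17357031 in wild-type replicate 2. GC content and transcript length are argued against for the cell cycle list: genes matched on both had a median of -0.007, against -0.76. Of 10000 lists drawn from the matched genes the lowest median was -0.29. Those lists hold unrelated genes, whereas cell cycle genes vary together (estimated correlation 0.689), so their spread is no measure of chance. The other lists were not matched in this way. A smaller share of cycling cells may underlie the falls, and all 35 genes had negative changes, but lower expression per cell would give the same. A response of the cells to loss of host MAVS stays open and was not tested apart from cell composition.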
